A study of Mus musculus with 2 samples.

How the data were processed

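MicroRNA sequencing was applied to adrenal gland tissue of 4-day-old female mice of the strain B6CASTF1/J. These are first-generation hybrids of a C57BL/6J and a CAST/EiJ parent. The labels give 2 libraries of 1 group, numbered as biological replicates 1 and 2 and described as different females. Both carry the same donor identifier, which leaves open whether it names an animal or the strain. They were treated as 2 animals. They state a size range under 30 and refer to a general protocol for multiplexed miRNA libraries. The series therefore held no comparison between conditions. The questions open to it were which miRNAs the neonatal adrenal tissue held, and how closely the libraries of 2 animals matched.

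The authors deposited, for each library, whole-number read counts per miRNA gene, with no normalization. Per the file headers, the assembly was mm10 and the annotation was GENCODE M21. The aligner, the counting tool and their versions are not given in the sources used here. Each table held 3 count columns and 4 leading rows of reads that name no gene. The 3 columns held reads on either strand, on the annotated strand of the gene and on the opposite strand. This assignment was read from the values, since the tables have no header. The column for the annotated strand was used for each main result. All 2202 gene identifiers were found among the miRNA genes of GENCODE M21, from which symbols and positions were taken. The reference genome used for positions was of the same build (GRCm38, also called mm10).

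The leading rows were kept out of library sizes and tests. Of 11704395 reads in replicate 1, 42.4% were assigned to miRNA genes, 25.8% were unmapped, 25.9% mapped to several places and 5.96% fell in no annotated miRNA gene. Of 11288855 reads in replicate 2, these shares were 39.9%, 26.1%, 27.8% and 6.24%. Reads that map to several places were not counted for any gene. A miRNA with identical copies at several loci is therefore undercounted, up to the point of having almost no reads. To mark such genes, hairpin sequences were searched for runs of 18 bases shared with a hairpin elsewhere in the genome. Such a run was found for 1135 of the 2202 genes and for 96 of the 377 genes detected in both libraries. Counts of these genes, and of the families they belong to, are uncertain. Reads were assigned to hairpin genes, so the 2 arms of a hairpin were not told apart. A sequence difference between the CAST/EiJ allele and the reference can also lower the count of a gene in both libraries.

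CPM values (read counts scaled to a common total) were computed over the reads assigned to miRNA genes. A gene was called detected with at least 10 reads in both libraries. Shares of reads carry 95% Wilson intervals. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. The widest such interval of a list share reached 0.0375 percentage points to either side. Agreement between the libraries was measured by Pearson and Spearman correlation of log2(CPM + 1) across genes, which are not independent replicates, with an interval from 1000 bootstraps over genes. The biological coefficient of variation (BCV) was the square root of the common dispersion of edgeR 4.0.16 under a design with an intercept alone, with TMM factors (1.05 for replicate 1 and 0.956 for replicate 2). Its interval came from 100 bootstraps over genes.

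Differences between the 2 libraries were tested per gene with an exact two-sided binomial test of the split of its reads against the split of TMM-scaled library sizes. P-values were adjusted by Benjamini-Hochberg over the 377 genes, with calls at an adjusted p under 0.05. This test compares these 2 libraries and not conditions, and it takes counting error as the only error. With 1 library per animal and 2 animals, no test against the spread between animals exists. The nearest substitute was edgeR's exact test with each library as a group of 1. Its dispersion is estimated from the same pair of libraries. Lists of miRNA genes were described by the percentile of the median log2 ratio of their detected members among 10000 random lists of equal size. Random members came from the 40 genes nearest in mean expression, and a list needed 3 detected members. A chi-square test over the detected genes (566135 on 376 degrees of freedom) showed that the tables are not copies of 1 library.

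The groups, the tests and 21 lists of miRNA genes were fixed before the data were examined. The lists were the let-7 family, miR-17/92 and its paralogous clusters, miRNAs studied in steroidogenic cells, the Hox cluster miRNAs, the miR-26, miR-29 and miR-30 families, 4 lists of imprinted or clustered loci (Dlk1-Dio3, Sfmbt2, other imprinted loci and the X-linked cluster of Mir322 and Mir503), and 12 lists of cell type or tissue markers. Those 12 were endothelial, mesenchymal and smooth muscle, erythroid, leukocyte, epithelial, kidney-enriched, liver-enriched, striated muscle, brown fat, neuronal and neuroendocrine, X-linked gonadal and pluripotent cell miRNAs. The rule for named genes took the 25 genes of highest mean CPM and up to 4 of the most abundant detected members of each list. It also took the 5 genes highest in each library over the other by log2 ratio, among called genes with a mean of at least 100 reads. It named 85 genes. A gene named outside the rule is said to be chosen after its values were seen.

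Alternatives were DESeq2 1.42.0 size factors or total miRNA reads in place of TMM, other read minimums, pseudocounts of 0.1 and 10, the counts of either strand, edgeR's exact test, shares without the most abundant gene, and each library left out where a value remained. Analyses ran in R 4.3.3 and Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6. The procedures were tested on simulated data. Counts for replicate 2 against replicate 1 were simulated over 381 genes with counting error alone (Poisson). In these the binomial test called 2.07% of 193 unchanged genes, 80.6% of 62 genes changed 1.5-fold, 93.8% of 65 changed 2-fold and 100% of 61 changed 4-fold. These rates do not cover the wider spread between the real libraries. A simulated BCV of 0.4 was estimated as 0.377 over 356 genes. Of 20 random lists of 7 genes with no shift, 2 fell below the 2.5th percentile. Of 20 lists shifted by -1.5 on the log2 scale, 19 did. The read-level files and signal tracks described beside the count tables were not used here.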

Results

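The adrenal gland joins a steroid-producing cortex and a catecholamine-producing medulla. Its miRNA profile was measured in 2 libraries of 1 group, from 4-day-old female hybrid mice. The labels describe the samples as different females but give both the same donor identifier, so the spread between the libraries is taken as that between animals on the description alone. Reads assigned to the annotated strand of miRNA genes numbered 4960537 in replicate 1 and 4506482 in replicate 2. With no other group in the series, the data describe the composition of the miRNA pool and the differences between these 2 libraries.

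A small set of miRNA genes held most of the reads. The 10 most abundant genes took 49.5% ± 1.88 (SD, n = 2) of the miRNA reads, and the 25 most abundant took 75.1% ± 1.12 (SD, n = 2). Mir126a, an endothelial miRNA encoded within Egfl7, ranked first with 105771 CPM ± 72212 (SD, n = 2). Its level differed widely between the libraries, at 15.7% of the reads in replicate 1 (95% Wilson interval 15.65 to 15.72) and 5.47% in replicate 2 (5.45 to 5.49). Mirlet7g (78935 CPM ± 4948, SD, n = 2) and Mirlet7i (65859 CPM ± 7581, SD, n = 2) followed, both members of a family linked to differentiation. This ranking is of uniquely mapped reads and does not place miRNAs with several gene copies. For example, 5 let-7 genes, among them Mirlet7a-1 and Mirlet7c-1, had at most 496 CPM in either library (chosen after their values were seen). Mir10a, which lies in a Hox gene cluster, was nearly level between the libraries at 46348 CPM ± 48.5 (SD, n = 2). Mir375, known from neuroendocrine and pancreatic islet cells, reached 38702 CPM ± 3285 (SD, n = 2). Mir23b, Mir322, Mir143, Mir23a and Mir10b completed the leading 10, with mean values from 28549 to 38496 CPM.

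Of 2202 annotated miRNA genes, 411 had at least 10 reads in replicate 1, 392 in replicate 2 and 377 in both. A further 1371 genes had 0 reads in both libraries. The hairpins of 956 of these share runs with others, and 0 sets no limit to their level. For the remaining 415 it allows a share of uniquely mapped miRNA reads of up to 6.05e-05% in replicate 1 and 6.66e-05% in replicate 2. At 0 or near it were also genes whose mature sequence exists in more than 1 copy. Mir1a-1 had 1 read in each library, and Mir133a-1 had 0 and 3 (both chosen after their values were seen). Reads that map to several places were not counted for any gene, so these values say nothing of the level of the mature miRNA.

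Mir126a lies on chromosome 2 (26591357 to 26591429, plus strand, mm10), within an annotated exon of Egfl7. Mirlet7g lies on chromosome 9 (106178840 to 106178927, plus strand) in an intron of Wdr82. Mir10a lies on chromosome 11 (96317165 to 96317274, plus strand), outside any other annotated gene on its strand. Mir10b lies on chromosome 2 (74726070 to 74726137, plus strand) in an intron of Hoxd3. Mir375 lies on chromosome 1 (74900658 to 74900721, minus strand), outside any other gene on its strand.

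**Figure D1:**
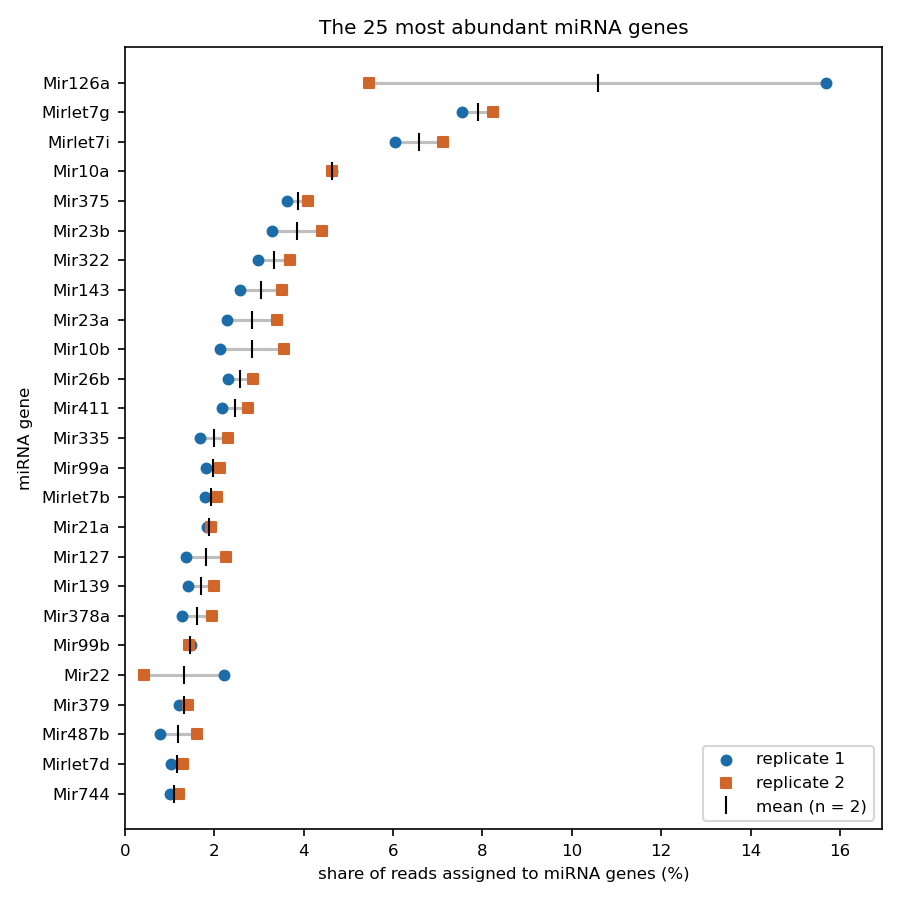
Share of the miRNA reads (%) for the 25 most abundant miRNA genes, with replicate 1 as circles, replicate 2 as squares and the mean as a black tick. Mir126a stands apart at 15.7% and 5.47%, and Mir22 is the other gene with a clearly larger share in replicate 1.

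Grouped by lists, the let-7 family and the imprinted Dlk1-Dio3 cluster were major parts of the pool in both animals. The 12 let-7 genes took 18.4% and 20.8% of the reads in replicates 1 and 2 (mean 19.6% ± 1.66, SD, n = 2). For 9 of these 12 genes the hairpin shares a run with another, so the share is uncertain. With all such hairpins of any gene removed from the list and from the total, the list held a mean of 3.95% of the smaller total. The Dlk1-Dio3 cluster on chromosome 12 is a large group of miRNAs expressed from the maternal chromosome. Its 56 genes took 10.6% and 14.3% (mean 12.5% ± 2.62, SD, n = 2), led by Mir411 (24662 CPM ± 4155), Mir127 (18175 CPM ± 6332), Mir379 (13152 CPM ± 1506) and Mir487b (12021 CPM ± 5863; SD, n = 2 for each). Other imprinted loci took 2.14% and 2.80%, most of it from Mir335 in an intron of Mest (19970.0 CPM ± 4296, SD, n = 2). The Sfmbt2 cluster families took 0.141% and 0.172%, with 7 of their 81 genes detected. The hairpins of 80 of those 81 genes share runs, so this share is uncertain too. The X-linked cluster of Mir322 and Mir503 took 3.73% and 4.45%, led by Mir322 (33333 CPM ± 5094, SD, n = 2).

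Lists of cell type or tissue markers and of miRNA families and clusters took very different shares of the reads. Endothelial miRNAs took 17.1% and 7.51% (mean 12.3% ± 6.81, SD, n = 2), of which Mir126a made up 15.7% and 5.47%. Without Mir126a in the list or the total, the mean was 1.94%, led by Mir139 (17087 CPM ± 4092, SD, n = 2). Neuronal and neuroendocrine miRNAs took 4.13% and 4.66%, of which Mir375 made up the greater part. The hairpins of 14 of the 18 genes of this list share runs and 6 genes were not detected, so both statements hold for uniquely mapped reads. Mir7b (3787 CPM ± 602) and Mir137 (712 CPM ± 24.7; SD, n = 2 for both) were further members. MiRNAs studied in steroidogenic cells took 3.48% and 2.85%, led by Mir21a (18888 CPM ± 591) and Mir125a (8280 CPM ± 4463; SD, n = 2 for both). Mesenchymal and smooth muscle miRNAs took 3.05% and 3.77%, led by Mir143 (30490 CPM ± 6565, SD, n = 2). The Hox cluster miRNAs took 7.14% and 8.40%. The miR-26, miR-29 and miR-30 families took 4.76% and 4.63%, with Mir26b at 25835 CPM ± 3920 (SD, n = 2). Runs are shared by the hairpins of 10 of the 13 genes of these families. The same holds for 7 of the 16 genes studied in steroidogenic cells, so these 2 lists have uncertain shares. The miR-17/92 and paralogous clusters, linked to proliferation, took 1.26% and 0.984%. The brown fat list took 1.30% and 1.98%, almost all from Mir378a, an intronic miRNA of Ppargc1b. Its hairpin shares runs with 2 others, and with all such hairpins removed from the list and from the total its mean was 0.0407% of the smaller total.

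MiRNAs of other tissues took smaller shares of the uniquely mapped miRNA reads. Leukocyte miRNAs took 0.197% and 0.224%, with Mir142 at 604 CPM ± 107 (SD, n = 2). The liver-enriched list held a single gene, Mir122, at 0.145% and 0.264%. Erythroid miRNAs took 0.106% and 0.0287%, epithelial miRNAs 0.471% and 0.116%, kidney-enriched miRNAs 0.0424% and 0.0182%, and striated muscle miRNAs 0.125% and 0.869%. Runs are shared by the hairpins of 6 of the 10 striated muscle genes and 3 of the 6 kidney-enriched genes, so these 2 shares are uncertain. The clusters known from pluripotent cells (Mir290 to Mir295 and Mir302) took 0.0408% and 0.0469%, with Mir293 at 119 CPM ± 32.8 (SD, n = 2). None of the 19 X-linked gonadal miRNA genes was detected by the read minimum. Together they had 36 reads in replicate 1 and 18 in replicate 2. Of the 21 lists, 11 took at least 1% of the reads in both libraries.

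**Figure D2:**
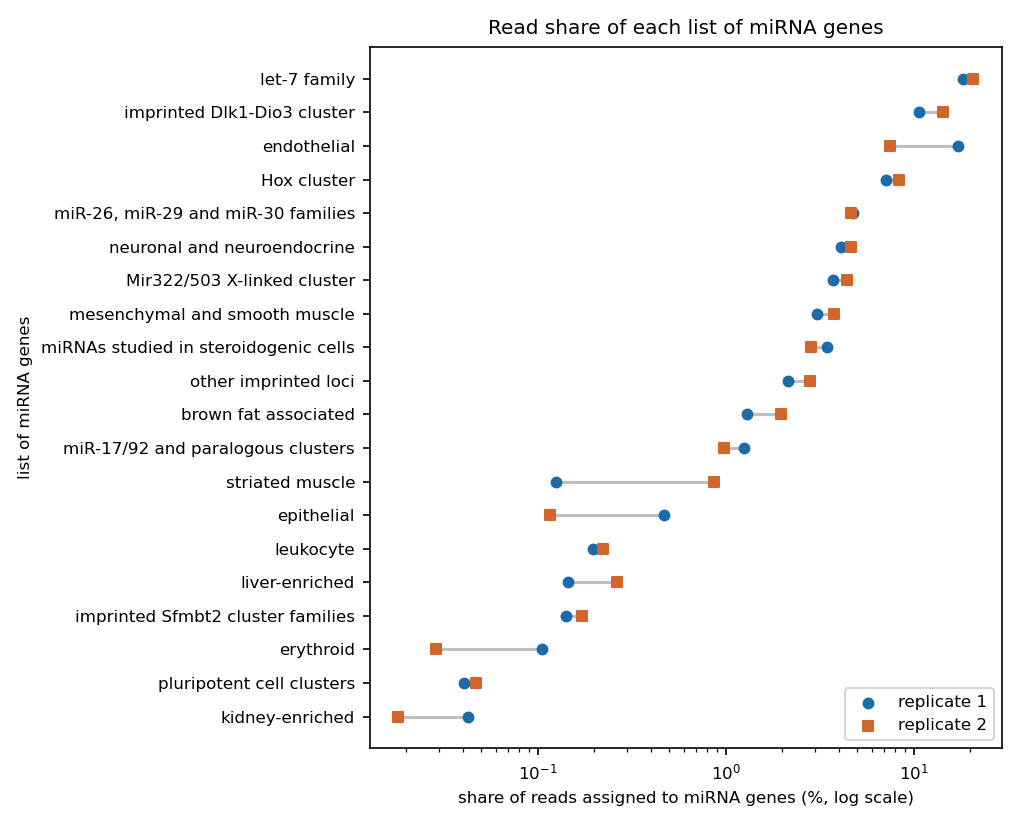
Share of the miRNA reads (%, log scale) taken by each list with a detected member, with replicate 1 as circles and replicate 2 as squares. The let-7 family leads at 18.4% and 20.8%, while the striated muscle, epithelial, erythroid and kidney-enriched lists lie below 1% with the libraries far apart.

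The libraries shared the ranking of miRNA genes but differed at many single genes. Across the 377 detected genes, Pearson's r of log2(CPM + 1) was 0.965 (95% bootstrap interval 0.954 to 0.975) and Spearman's rho was 0.962. The log2 ratio of replicate 2 over replicate 1 had an SD of 0.97 across genes. Ratios stayed within 1.5-fold at 236 genes and reached at least 4-fold at 20. The common BCV was 0.433 (95% bootstrap interval 0.370 to 0.482), a measure of the spread between these 2 animals, their dissection and their library preparation together.

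Folds and log2 ratios between the libraries are of TMM-scaled reads, whereas CPM values are not TMM-scaled, so ratios of the printed CPM values differ from the folds by 0.13 on the log2 scale. By more than counting error, 257 of the 377 genes differed (exact binomial test, adjusted p under 0.05). Of these, 123 were higher in replicate 1 and 134 in replicate 2. A ratio of at least 2-fold was held by 69 of them, 45 higher in replicate 1 and 24 in replicate 2. Set against the spread of the pair itself, with edgeR's exact test at the common dispersion, 7 genes passed, all higher in replicate 1, and 24 had an unadjusted p under 0.05. That test takes its dispersion from the same pair, so it shows which genes stand out from the general spread of these libraries, and the binomial calls cover counting error alone. Scaling by total miRNA reads in place of TMM shifted every log2 ratio by -0.13 and gave 144 genes higher in replicate 1 and 112 higher in replicate 2, with the direction flipped at Mir17, Mir99b and Mir191 (the last chosen after its values were seen).

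The miR-200 family, typical of epithelial cells, gave the largest differences of the rule for named genes in replicate 1. Its 5 members, from 2 loci, had 20952 reads in replicate 1 and 865 in replicate 2. Mir200b was 30.4-fold higher in replicate 1 by TMM-scaled reads (log2 ratio of replicate 2 over replicate 1 -4.92, 95% exact interval -5.11 to -4.74), with unscaled values of 1822 and 54.8 CPM. Mir141 was 27.8-fold higher, Mir200c 20.6-fold, Mir429 14.4-fold and Mir200a 11.2-fold. These 5 were among the 7 genes past edgeR's exact test. The other pair, Mir195a and Mir301, was chosen after its values were seen and was 9.98-fold and 10.6-fold higher in replicate 1. Mir200b, Mir200a and Mir429 lie on the minus strand of chromosome 4 (156053905 to 156055750) in an intron of Ttll10. Mir200c and Mir141 lie on the minus strand of chromosome 6 (124717914 to 124718390) in an intron of Gm15884.

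Of the 7 detected epithelial genes, 6 were higher in replicate 1 and 1 in replicate 2. The exception was Mir203, a miRNA of keratinocytes, which was 2.38-fold higher in replicate 2. The list median of -3.85 lay below all 10000 random lists (percentile 0). Of the 4 detected kidney-enriched genes, 3 were higher in replicate 1, among them Mir192 (6.25-fold) and Mir194-2 (3.64-fold), neighbours on chromosome 19. Mir204 was 1.24-fold higher in replicate 1, and Mir190a had 43.5 and 34.4 CPM with no call, though it was called higher in replicate 1 under total reads. The hairpins of Mir194-2 and Mir190a share runs with others, so their counts hold uniquely mapped reads alone. The list median was -1.09 (percentile 1.26). With a mean of at least 100 reads all 4 members stay (percentile 1.35). With at least 100 reads in both libraries it was -0.32 (percentile 18.1), but that minimum removes Mir194-2 (250 and 57 reads) for being low in replicate 2. Among the 3 detected erythroid genes, Mir451a and its neighbour Mir144 were each 3.66-fold higher in replicate 1, whereas Mir486 was 1.49-fold higher in replicate 2. The list median was -1.87 (percentile 0.51), a value set by this pair of neighbours.

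Striated muscle miRNAs went the other way. Mir206, a miRNA of skeletal muscle, had 1239 CPM in replicate 1 and 8627 CPM in replicate 2, and was 7.62-fold higher in replicate 2 by TMM-scaled reads (log2 ratio 2.93, 95% exact interval 2.89 to 2.97). Mir499, in an intron of the myosin gene Myh7b, was 9.38-fold higher in replicate 2, and Mir208b, in an intron of Myh7, was 3.55-fold higher. All 3 detected members were thus higher in replicate 2 (median 2.93, percentile 100). None of them passed edgeR's exact test. Below the read minimum, Mir133b had 9 and 29 reads, whereas Mir1b had 18 and 4 (both chosen after their values were seen). Mir26a-1 (8.90-fold), Mir493 (4.33-fold) and Mir380 (3.05-fold) completed the 5 genes named for the largest ratios towards replicate 2. The hairpin of Mir26a-1 shares a run with another hairpin.

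**Figure D3:**
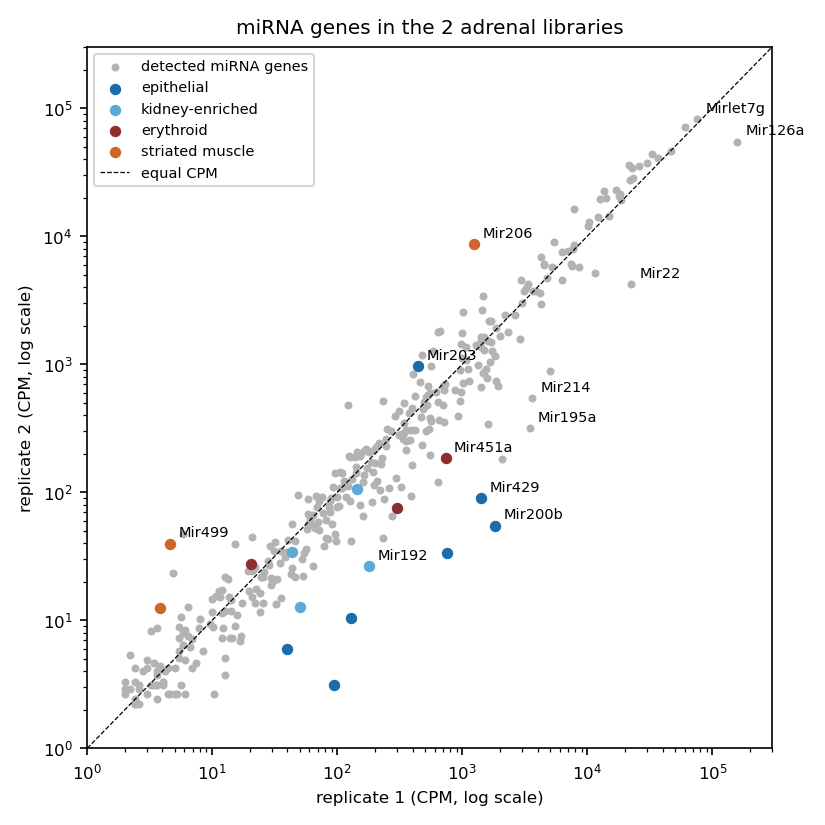
CPM of each of the 377 detected miRNA genes in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), with 4 lists in colour and the dashed line at equal CPM. The miR-200 genes lie far below the line and Mir206 and Mir499 above it, and Mir126a and Mir22 lie below it among the abundant genes.

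The imprinted Dlk1-Dio3 cluster was shifted towards replicate 2. Of its 50 detected genes, 31 were higher in replicate 2, 14 in replicate 1 and 5 had no call. The counts were 27 and 16 under scaling by total reads. Single members ran from Mir666 (log2 ratio -0.90, chosen after its values were seen) to Mir493 (2.11). Mir127 was 1.81-fold and Mir487b 2.25-fold higher in replicate 2. The median of 0.29 was above the range of -0.20 to 0.16 that holds the middle 95% of random lists (percentile 100). All 7 detected genes of the Sfmbt2 families were higher in replicate 2, 6 under total reads, with a median of 0.63 (percentile 99.9). All 7 share runs with other hairpins. Of the 11 detected genes of the pluripotent cell clusters, 5 were higher in replicate 2 and none in replicate 1 (median 0.53, percentile 99.8). With members of at least 100 reads in both libraries the median was 0.23 (percentile 90.3), with a mean of at least 100 reads it was 0.23 (percentile 94.4), and without hairpins that share runs it was 0.36 (percentile 96.2). In all, 7 of 19 lists lay outside the middle 95% of random lists. The count was 4 with members of at least 100 reads in both libraries, where striated muscle kept 1 member, too few to test. It was also 4 without hairpins that share runs, where the kidney-enriched list kept 2 members and the Sfmbt2 list 0, again too few. Members of a cluster or family are not independent of each other, whereas random lists draw genes singly. The percentiles can therefore overstate how far such a list stands out, and the count of lists was not set against chance.

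For the other lists the median was inside that range, though most held called genes. Of the let-7 family, 9 genes were higher in replicate 2 and 1 in replicate 1. In the miR-17/92 and paralogous clusters 6 were higher in replicate 1 and 2 in replicate 2, or 5 and 2 adjusted over the list alone. Mir92-1 was 1.53-fold higher in replicate 1, whereas Mir93 was 1.21-fold higher in replicate 2. Counts adjusted over the list alone were the same as those over all genes for each of the other lists with a detected gene. Of the genes studied in steroidogenic cells, 7 were higher in replicate 1, with Mir125a at 2.04-fold, and 5 in replicate 2. Of the neuronal and neuroendocrine genes, 5 were higher in replicate 1 and 4 in replicate 2, with Mir375 1.23-fold higher in replicate 2. Mir126a (2.62-fold) and Mir222 (1.21-fold) of the endothelial list were higher in replicate 1, and Mir139 (1.54-fold) and Mir221 (1.37-fold) in replicate 2. Mesenchymal and smooth muscle members were split in the same manner. Mir214 was 6.13-fold higher in replicate 1, with 2 more genes, whereas Mir145a (2.98-fold) and Mir143 (1.49-fold) were higher in replicate 2.

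In the miR-26, miR-29 and miR-30 families 8 genes were higher in replicate 1 and 3 in replicate 2, with Mir30d 1.35-fold higher in replicate 1 and Mir26b 1.36-fold higher in replicate 2. The Hox cluster list had 3 and 2, with Mir196b 2.30-fold higher in replicate 1 and Mir10b 1.82-fold higher in replicate 2. The list of the Mir322 and Mir503 cluster had 2 and 3, the leukocyte list 1 and 3, and the brown fat list 1 and 2. Of the other imprinted loci, 3 genes were higher in replicate 2 and none in replicate 1, with Mir483 at 2.70-fold. Mir122, the liver-enriched gene, was 1.99-fold higher in replicate 2. Mir22 was 4.84-fold higher in replicate 1 and, after Mir126a, the only other of the 25 most abundant genes called higher there. Under total reads Mir99b was called so as well.

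**Figure D4:**
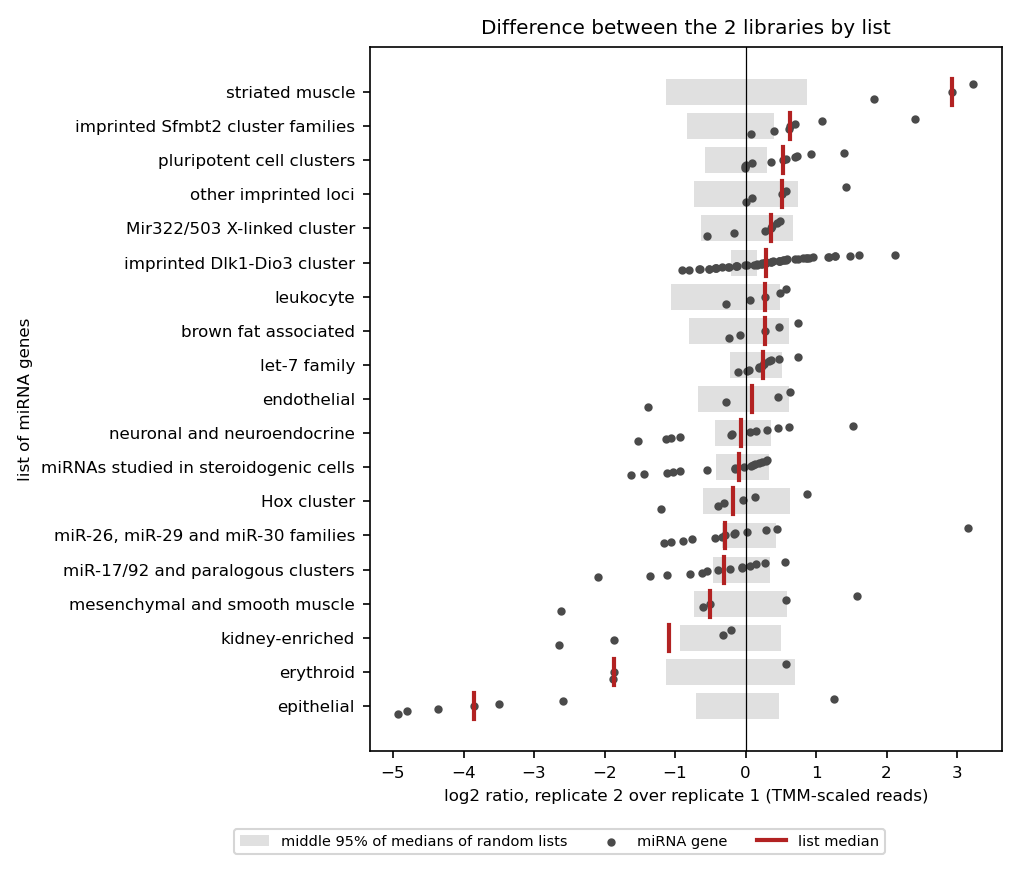
Log2 ratio of replicate 2 over replicate 1 (TMM-scaled reads) for each detected gene of the 19 lists with at least 3 such genes, as points, with the list median in red and the middle 95% of medians of random lists in grey. The epithelial (-3.85), erythroid (-1.87) and kidney-enriched (-1.09) medians lie left of the grey range, and striated muscle (2.93), Sfmbt2 (0.63), pluripotent cell (0.53) and Dlk1-Dio3 (0.29) medians lie right of it.

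Reads on the strand opposite to miRNA genes made up 17.0% of the strand-assigned reads in replicate 1 (95% Wilson interval 17.00 to 17.06) and 9.94% in replicate 2 (9.91 to 9.97). Nearly all came from genes that overlap another miRNA gene on the other strand, such as Mir126a with Mir126b. Over the 2138 genes without such a partner the share was 0.00342% in replicate 1 (0.00289 to 0.00405) and 0.00392% in replicate 2 (0.00335 to 0.00458).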

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

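The count column of the strand opposite to each gene was not part of the comparisons. Over 4 of the 2138 miRNA genes that overlap no miRNA gene on the other strand, it held more reads in both libraries than the 3 that a count of 0 allows. These genes were found by their values. Mir203 (chromosome 12, 112130880 to 112130955) had 46 and 55 opposite-strand reads in replicates 1 and 2, beside 2210 and 4356 on its own strand. Mir708 (chromosome 7, 96249424 to 96249532) had 16 and 20 beside 3512 and 2813. Mirlet7b had 6 and 13 beside 88795 and 93013. Mir7654 (chromosome 8, 8690093 to 8690162) had 5 and 4 beside 2 and 5. No explanation for these reads was tested. The group had 2 libraries, too few for a search for outlying samples, and there was no other group to set against it.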

How the results depend on the processing

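The alternatives without hairpins that share runs, without genes that overlap another miRNA gene, with at least 10 reads in either library and with a minimum of a 2-fold ratio, a mean of at least 100 reads for list members, both read minimums on members outside the miR-200 family, and the strand share without each replicate, were chosen after seeing the data. Of 41 values of the main results under an alternative, 35 stayed: counts within 1.5 times, shares within the SD of the libraries, and correlation and BCV within the bootstrap interval of the main value. Some of these could not fail. With n = 2, the share of either library lies within their SD of the mean, apart from the top 10 being chosen anew. A common shift of all ratios, as another scaling gives, leaves the percentiles and so the count of lists unchanged. The replicate correlation rose to 0.981, above its interval, over all genes with a read in either library; the cause was not tested. The count of differing genes fell from 257 to 7 with edgeR's exact test, which by its construction adds the dispersion of the pair, and to 69 with the 2-fold minimum, which removes small ratios. It lay between 218 and 274 under the other alternatives. The count of lists outside the range of random lists fell from 7 to 4 with members of at least 100 reads in both libraries (1 list had too few members left, 2 moved inside) and to 4 without hairpins that share runs (2 had too few, 1 moved inside). It was 5 with a mean of at least 100 reads (1 and 1). The mean opposite-strand share fell from 13.5% to 0.00367% without genes that overlap another miRNA gene, which by construction removes reads of the overlapping partner. BCV ran from 0.424 to 0.468 over its alternatives. Without each replicate in turn, detected genes ran from 392 to 411, the top 10 share from 48.2% to 51.0%, lists with at least 1% from 11 to 12, and the opposite-strand share from 9.94% to 17.0%. Correlation, BCV, differing genes and list differences have no value with 1 library. No paired analysis was possible because the series had 1 group.

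Of the other values (shares and medians of single lists and ratios of 10 genes), 207 stayed. Among these are list shares without 1 replicate and list medians under other scalings, whose label could not change by construction. A further 32 shares moved by more than the spread of the libraries, 5 list medians left their call and no called median changed sign. Medians inside the range of random lists changed sign in 3 lists. Mesenchymal and smooth muscle went from -0.51 to 0.57 without hairpins that share runs, neuronal and neuroendocrine from -0.07 to between 0.05 and 0.18 under 4 alternatives, and endothelial from 0.09 to -0.04 under total reads. With either-strand counts, where reads of Mir126a and Mir378a are ambiguous, the endothelial mean share was 2.06% and the brown fat share 0.0353%. TMM calls of 257 genes lost 9 and flipped 0 with DESeq2 size factors, which shift ratios by -0.06, and lost 19 and flipped 3 with total reads. Depth limits the low lists most: Mir141 had 14 reads in replicate 2, and Mir208b had 19 in replicate 1.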

Other observations

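The tests on miR-200 alone, on epithelial or kidney tissue, on striated muscle, on the family of miR-1 and miR-206 alone, on counting error and on mature sequence were chosen after the differences had been seen. The test on hairpin GC content was set before its result was seen. All families, clusters and genes named here beyond the rule for named genes were chosen after their values were seen.

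In some families, picked for this after their values were seen, related miRNAs from separate loci differed between the libraries in the same direction, whereas other families were split. All 6 genes taken here from the miR-15 family (Mir15a, Mir15b, Mir16-1, Mir16-2, Mir195a and Mir497), which restrain cell cycle genes, were higher in replicate 1 by the binomial test. Their ratios ran from 1.56-fold (Mir16-2) to 9.98-fold (Mir195a). These 6 genes come from 3 loci and together took 1.27% of the reads in replicate 1 and 0.301% in replicate 2. Mir16-1 and Mir16-2 are copies of 1 miRNA, and reads that map to both were not counted. Their counts and folds, and the total, therefore hold for uniquely mapped reads alone and do not give the level of mature miR-16. Mir322, often grouped with this family but left out of the set, took 2.97% and 3.69% and was 1.36-fold higher in replicate 2. The direction and the total therefore hold for the 6 genes and not for the whole family. The 3 members of the miR-148 family (Mir148a, Mir148b and Mir152), from 3 loci, were 2.07-fold to 4.86-fold higher in replicate 1. The 4 members of the miR-130 family (Mir130a, Mir130b, Mir301 and Mir301b) were 1.17-fold to 10.6-fold higher in replicate 1. Mir23a and Mir23b, from 2 loci, were both higher in replicate 2, together at 5.58% and 7.83% of the reads. Their hairpins share a run. Among the split families, Mir193a was 1.39-fold higher in replicate 2 and Mir193b 1.18-fold higher in replicate 1. Mir26a-1 was 8.90-fold higher in replicate 2 and Mir26a-2 2.23-fold higher in replicate 1. The hairpin of Mir26a-1 shares a run with another, so its count holds uniquely mapped reads alone. The Mir26a pair therefore does not show that the mature miRNAs differed in direction. Scaling by total reads moves ratios by -0.13, less than any of these miR-15 or miR-148 differences.

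Mir802, on the plus strand of chromosome 16 (93369720 to 93369816), had 1298 reads in replicate 1 and 1 in replicate 2. The ratio was 1077-fold, with a 95% exact interval from 193-fold to 42564-fold for counting error. Mir6969, in an intron of the pancreatic colipase gene Clps on chromosome 17, had 24 reads in replicate 1 and 0 in replicate 2. Mir802 is known from liver, pancreas and kidney. Mir122, the liver miRNA, was higher in replicate 2. So was Mir375, known in part from pancreatic islet cells, at 1.23-fold. No tissue source was tested for these genes.

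Epithelial miRNAs other than Mir203, and 3 of 4 detected kidney-enriched miRNAs, were higher in replicate 1, though the kidney-enriched median lost its call (-0.32, percentile 18.1) with at least 100 reads in both libraries, a minimum that removes Mir194-2 for being low in 1 library, and kept it with a mean of at least 100 reads (percentile 1.35). The 6 detected members outside the miR-200 family (Mir203, Mir205, Mir190a, Mir192, Mir194-2 and Mir204) had a median log2 ratio of -1.09. It lay at percentile 0.19 of random lists and 0.30 among genes with a mean of at least 100 reads. Mir205, Mir192 and Mir194-2 had already been called higher in replicate 1. The median therefore restates the pattern and is no separate test of an effect on the miR-200 sequences alone. It also rests on Mir205 and Mir194-2, with 27 and 57 reads in replicate 2: the 4 members left by the same minimum in both had a median of -0.26 (percentile 24.4). The hairpin of Mir194-2 shares a run with another, so its count holds uniquely mapped reads alone. Mir192 and Mir194-2 are also neighbours that were counted separately. A candidate explanation that stays open is epithelial or kidney tissue taken with the gland of replicate 1: of the 11 detected members, 9 were higher there, but that count restates the pattern, and the bound of 9 was set with the values in view. None of the 13 listed genes is on another list, 9 of the 11 reach 10 CPM in both libraries, and the most abundant reached 1822 CPM (Mir200b) and 181 CPM (Mir192) in replicate 1; a difference between the 2 animals or in library preparation was not tested.

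Striated muscle miRNAs were higher in replicate 2. The difference was not confined to the family of miR-1 and miR-206. Outside it, Mir133b, Mir208b and Mir499 together had 51 reads in replicate 1 and 264 in replicate 2, a scaled ratio of 6.24 (95% exact interval 4.61 to 8.60). Mir499 (23 and 179 reads) and Mir208b (19 and 56) had already been called higher in replicate 2. The pooled ratio therefore restates the pattern and is no separate test of an effect on these sequences. Muscle tissue in the replicate 2 sample may be the source and stays open: all 3 detected members of the 10 listed were higher there, but this too restates the pattern. The muscle miRNAs that would be most abundant, miR-1a and miR-133a, have several gene copies and near 0 counted reads (at most 5 for any copy), and Mir1b, with 18 and 4 reads, went the other way. None of the 10 genes is on another list, only Mir206 reaches 10 CPM in both libraries, and a difference between the animals was not tested.

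Members of 1 cluster differed between the libraries by unequal folds, although neighbours can come from 1 transcript: in the Mcm7 cluster Mir106b was 4.28-fold and Mir25 2.56-fold higher in replicate 1, whereas Mir93 was 1.21-fold higher in replicate 2. Counting error alone is argued against, since 91 of 106 neighbouring pairs differed in ratio (adjusted Fisher's exact p under 0.05). So is a general effect of hairpin GC content, with a Spearman rho of -0.0768 across 283 genes (95% bootstrap interval -0.195 to 0.0431, genes not independent). Neither GC differences within clusters nor the GC content of the sequenced arms was tested. An effect tied to the mature sequence, as library preparation could give, stays open: the median difference between members was 0.65 (log2) in 30 clusters and 0.41 in 30 families of similar sequence, with a permutation p of 0.148 for the difference of these medians. With ratios shuffled over genes, the lower 2.5th percentile was 0.56 for clusters and 0.53 for families, so families alone lay below it. Some families held gene copies of 1 miRNA, such as Mir26a-1 with Mir26a-2 and Mir16-1 with Mir16-2. Reads that map to both copies were not counted, so such pairs do not compare the shared mature sequence. The comparison therefore cannot decide on an effect tied to that sequence. No biological explanation was tested, since the design has 1 group.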
